A study of Danio rerio with 30 samples.

How the data were processed

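Total RNA from all tissue in front of the gills of AB zebrafish was measured on 30 Affymetrix ZebGene 1.0 ST arrays after the GeneChip WT PLUS kit. Each array holds 1 pool of 5 fish, with 3 arrays for each of 10 groups, a standard control or a grb10a knockdown morpholino at 5, 10, 15, 20 or 30 dpf. The values deposited by the authors are log2 signals per probe set, made with RMA per the submitters' processing notes; the version and settings are not given in the sources used here. They range from 0.987 to 14.2, and no further normalization was applied. A spread between arrays is a spread between pools, so p-values reflect differences between pools and not between single fish.

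Probe sets were matched to gene symbols through the array annotation, and current symbols were found by Entrez identifier for 20323. The 20806 probe sets with 1 symbol (27.7%) were kept, 855 with several symbols and 53551 without a name were left out of the gene tests. For 1365 symbols with several probe sets the one with the highest mean signal was used, which left 19260 genes. Detection calls were not used here; genes whose mean signal lay in the lowest 33.3%, under 6.06, were marked as dim and left out in an alternative. The median SD within groups was 0.188. The first 3 principal components held 42.1%, 16.9% and 5.43% of the variance.

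Differences were tested with limma 3.58.1 in R 4.3.3 with the data.table package, version 1.17.8, with 1 mean per group over all 30 arrays and 20 residual degrees of freedom; the moderated variance had 6.05 prior degrees of freedom. Contrasts were knockdown minus control at each age, the mean of these 5 contrasts, the F test of their 4 differences from 5 dpf, and controls at 30 dpf minus controls at 5 dpf. All tests are two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes of a contrast with a threshold of 0.05. The replicate numbers are names in the labels, so no block was used.

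Gene lists, 17 of pathways and 20 of tissues in or beside the head, were fixed before the data were examined, as were the contrasts, the alternatives and the rule for named genes unless the text says otherwise. They held 1480 genes, of which 1269 were measured. For each list of at least 5 measured genes, the members that rose, fell or passed neither way were counted from the test over all genes, and again with p adjusted over the list alone. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 37 lists of a contrast. Camera with an estimated correlation and the rotation test fry stand beside it.

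Named genes were grb10a first, then at each age the 10 largest rises and the 10 largest falls among genes past the threshold whose 3 knockdown arrays lay outside the range of the 3 control arrays. For the mean contrast the difference had to have 1 sign at all 5 ages. Clone-based symbols were passed over. Of these genes the text gives a part, chosen after their values were seen; genes given as examples of a list are among its 4 members with the smallest p, and other list members were chosen after their values were seen. The visceral score of an array is the mean signal of the exocrine pancreas, liver and intestine lists.

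Alternatives were an intensity trend with robust spread, leaving out dim genes, a second quantile normalization, median centring of each array, all probe sets of a gene or all probe sets one by one, array quality weights, the replicate number as a block, only the compared arrays in the fit, and each array left out in turn. Added after seeing the data were the visceral score as a covariate, leaving out genes that follow it at other ages with a correlation over 0.5, leaving out 5 dpf, and 10 dpf as the start of the age comparison. The test was checked on simulated data with normal noise drawn independently for each gene. In each of 5 draws 200 of 19260 genes were changed at 30 dpf, and 4.69% of the calls were false. Other splits of the arrays were tested in full for 3 against 3 arrays, with 10 splits, and by 100 regroupings within each age for the mean contrast and the F test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.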

Results

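Transcripts were measured on 30 arrays from AB strain zebrafish, each hybridised with RNA from a pool of 5 fish. The tissue was everything in front of the gills, taken at ages of 5, 10, 15, 20 or 30 dpf (days after fertilisation). At each age 3 pools carried a splice-blocking morpholino against grb10a, an adaptor protein that binds insulin and insulin-like growth factor receptors. The series design places its target at the splice donor of coding exon 3, while the treatment notes also name a morpholino at exon 4, so the site blocked in these pools is taken from the design alone. The other 3 pools carried a standard control morpholino directed at human beta-globin, and the comparison asks which transcripts differ when grb10a is knocked down in early life. The median signal of an array over all probe sets lay between 5.51 and 5.63 (log2), and arrays of 1 group correlated at 0.968 to 0.99. The number of arrays limits the precision; group values are means ± SD over 3 arrays (n = 3), and differences are knockdown minus control on the log2 scale with their standard error (SE). "Rose" and "fell" stand only for an adjusted p under 0.05, and list members not counted as risen or fallen did not pass that test. Signals under 6.06, the limit of the lowest 33.3% of genes by mean signal, are taken as held up by background, which was not measured. A difference to or from a group mean under 6.06 is therefore read as a lower limit. In each gene named as among the largest changes of an age, all 3 knockdown arrays lay outside the range of the 3 control arrays.

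The signal of grb10a, read by 1 probe set (13074692), was higher in knockdown at 5 dpf and did not pass the test at the other ages. At 5 dpf it was 9.11 ± 0.16 in knockdown and 8.10 ± 0.10 in controls, a rise of 1.01 (SE 0.12, adjusted p = 3.59e-07), or 2.01-fold. The differences were 0.16 at 10 dpf (adjusted p = 0.537), 0.33 at 15 dpf (0.0615), -0.24 at 20 dpf (0.187) and -0.04 at 30 dpf (0.94). At 15 dpf leaving out control replicate 2 gave 0.38 and passed the test. The difference varied with age (F test of limma, adjusted p = 2.53e-05), and the difference at 20 dpf minus that at 5 dpf was -1.25 (adjusted p = 4.49e-06). A splice-blocking morpholino changes how the transcript is spliced and need not lower its total signal; the position of the probes relative to the blocked site is not given in the sources used here, so this probe set does not check the labels. The paralog grb10b fell by 0.90 at 10 dpf (adjusted p = 0.0016), from 7.88 ± 0.41 to 6.98 ± 0.15.

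**Figure D1:**
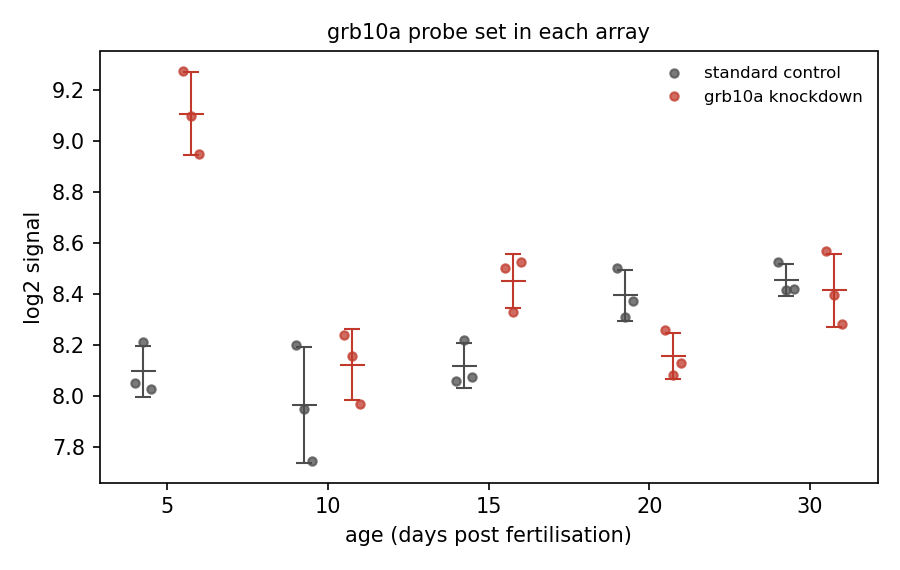
Log2 signal of the grb10a probe set (vertical axis) in each array by age in days post fertilisation (horizontal axis), with points for arrays and bars for the mean ± SD of 3 arrays in standard control (grey) and grb10a knockdown (red). The 3 knockdown arrays at 5 dpf, 8.95 to 9.28, lie above all other arrays, the highest of which is at 8.57.

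At 5 dpf genes made by the pancreas, liver and intestine were far lower in knockdown heads. The digestive proteases prss59.1, cpa5 and ctrb.3, secreted by the exocrine pancreas, fell, with differences of -6.39 (SE 0.61), -6.29 (SE 0.44) and -6.24 (SE 0.46). The lipoprotein genes apobb.1 and apoc2 were at -6.37 and -5.95, and fetub, a secreted liver protein, fell by 6.14 (SE 1.01) with a wide spread in knockdown (SD 3.01). Of the exocrine pancreas list 26 of 31 measured members fell, 27 when adjusted over the list alone, with a median of -4.02 (camera with an estimated correlation, adjusted p = 3.51e-05). Of the liver list 41 of 45 fell, also 41 when adjusted over the list alone (median -3.02, adjusted p = 6.3e-05 with an estimated correlation), and of the intestine list 24 of 33, 25 alone (median -1.22, adjusted p = 3.04e-05 with an estimated correlation). A visceral score, the mean signal of these 3 lists, was 8.09 ± 0.04 in controls and 5.39 ± 0.24 in knockdown at 5 dpf. At every later age its group means lay between 5.07 and 5.82 in both treatments.

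**Figure D2:**
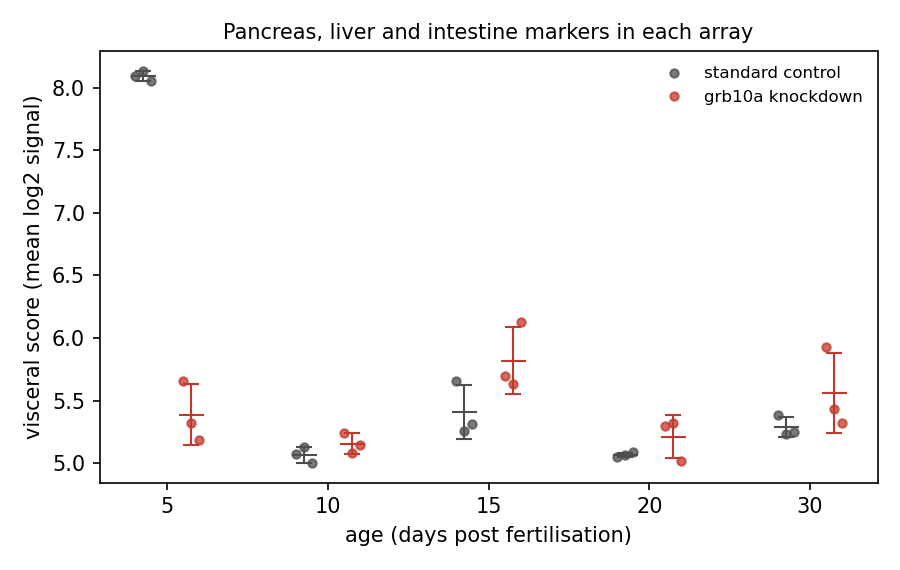
Visceral score, the mean log2 signal of the pancreas, liver and intestine lists (vertical axis), in each array by age in days post fertilisation (horizontal axis), with points for arrays and bars for the mean ± SD of 3 arrays in standard control (grey) and knockdown (red). The 3 control arrays at 5 dpf lie at 8.05 to 8.13 and all other arrays at 5.00 to 6.13.

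Muscle, kidney and fatty acid oxidation genes were lower at 5 dpf as well, beside the visceral score of 5.39 in knockdown against 8.09 in controls. Of 71 skeletal muscle genes 40 fell, 42 when adjusted over the list alone (median -0.69, adjusted p = 0.0184 with an estimated correlation). They include actn3a (-1.61), the skeletal actin acta1b (-1.68), the fast troponin tnni2b.2 (-1.55) and the myosin light chain myl1 (-1.26). Of 19 kidney genes 9 fell (median -0.47, adjusted p = 0.0181 with an estimated correlation), among them pdzk1 (-3.33) and cdh17 (-3.04). Of 29 fatty acid oxidation genes 14 fell, 20 when adjusted over the list alone (adjusted p = 0.0181 with an estimated correlation), with ucp1 at -3.08 and the carnitine transferase cpt1b at -0.76. Of 29 antioxidant and xenobiotic genes 12 fell, 14 alone (adjusted p = 0.0125 with an estimated correlation), with cyp3a65 at -4.50, the transporter abcc2 at -2.17 and nqo1 at -0.94. Among cholesterol synthesis genes 5 of 22 fell, 7 alone, with dhcr7 at -1.22 and tm7sf2 at -0.96 (camera adjusted p = 6.87e-05; adjusted p = 0.11 with an estimated correlation). Binding proteins of insulin-like growth factors also fell, igfbp1a at -1.32, igfbp2a at -1.15 and igfbp2b at -0.68, within an insulin list of which 1 of 39 rose and 6 fell (median 0.04, mean -0.08, camera adjusted p = 0.744).

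Photoreceptor genes were higher at 5 dpf, and the 2 arms of the circadian clock moved apart, beside the visceral score of 5.39 in knockdown and 8.09 in controls. Of 50 photoreceptor genes 18 rose, 26 when adjusted over the list alone (median 0.45, camera adjusted p = 1.32e-11; adjusted p = 0.163 with an estimated correlation). Examples are grk1b at 0.78 and the cone genes cnga3a at 0.75 and pde6c at 0.61. Neuron and lens genes were higher as well, with medians of 0.20 and 0.21 and 5 of 48 and 2 of 49 risen (camera adjusted p = 0.00282 and 0.0236; adjusted p = 0.521 and 0.609 with an estimated correlation). The pigment epithelium list had a median of -0.04 (camera adjusted p = 0.745). Of 39 circadian clock genes 12 rose and 3 fell, 14 and 9 alone (camera adjusted p = 0.0139; adjusted p = 0.521 with an estimated correlation). The transcription factors nfil3-2 and nfil3-5 rose by 1.31 (SE 0.17) and 1.14 (SE 0.17), rorcb by 0.95 and npas2 by 0.72. In arm lists chosen after seeing the data, 7 of 13 genes of the night arm rose (median 0.58), while of 18 genes of the day arm 3 fell and 2 rose (median -0.34), with nr1d1 at -0.83 and nr1d2b at -0.49 among the fallen. Among the largest rises were also samsn1a, an adaptor protein (1.26, SE 0.15), crybg2, of the beta/gamma crystallin family (1.06, SE 0.19), and the protocadherin pcdh2ab2 (1.12, SE 0.18).

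In all, 2308 of 19260 genes differed at 5 dpf, 1054 higher and 1254 lower. A change of at least 2-fold was found in 480 of the lower genes and 14 of the higher genes, and all 173 that changed at least 4-fold were lower. Median centring of the arrays gave 1763 higher and 1175 lower genes. Without control replicate 2 the count was 1538, and with only the 6 arrays of this age in the fit it was 1442 (388 higher, 1054 lower). An alternative chosen after seeing the data left out 301 genes that followed the visceral score in the 24 arrays of other ages, and 2163 of 18959 genes differed. It removed only 49 of 108 members of the 3 visceral lists, and of those left 24 of 28 liver, 14 of 21 intestine and 5 of 10 pancreas genes fell. It therefore does not free the count of visceral transcripts.

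At 10 dpf genes of cell division were higher in knockdown. The mitotic kinase cdk1 rose by 1.27 (SE 0.20, adjusted p = 0.000944), the spindle proteins kif11 and prc1b by 1.12 (SE 0.15) and 1.23 (SE 0.16), and the cytokinesis regulator ect2 by 1.11 (SE 0.14). Of 42 cell cycle genes 24 rose, 33 when adjusted over the list alone, with a median of 0.68 (camera adjusted p = 1.16e-30). This was the only list of the 13 called at this age that held with an estimated correlation (adjusted p = 0.0265). Its mean signal was 7.45 and 7.46 in knockdown replicates 1 and 2 but 7.05 in replicate 3, against 6.54 to 6.78 in controls. Knockdown replicate 3 was also nearer the controls than the other 2 in the muscle list (7.08 against 7.31 and 7.32, controls 6.94 to 7.05). The largest rise was in inhbb, the beta-B subunit of activin (1.61, SE 0.19, adjusted p = 6.53e-05), and the nuclear import factor kpna2 rose by 1.24 (SE 0.23).

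Genes lower at 10 dpf included clock genes and 2 genes of the insulin signalling list. The clock repressor bhlhe40 fell by 1.73 (SE 0.19, adjusted p = 2.33e-05), per3 was at -1.12 and nr1d2b at -0.89. Of 39 clock genes 7 fell, 13 when adjusted over the list alone (camera adjusted p = 8.22e-10; adjusted p = 0.159 with an estimated correlation). The insulin receptor substrate irs2a fell by 1.37 (SE 0.21, adjusted p = 0.000822). Of 39 insulin signalling genes 1 rose and 2 fell, irs2a and the paralog grb10b already given above. Adjusted over the list alone 2 rose and 6 fell (camera adjusted p = 0.00404; adjusted p = 0.275 with an estimated correlation). Falls were also found in the kinase mknk2b (-1.43, SE 0.22), the cGMP phosphodiesterase pde5aa (-1.34, SE 0.17), the Polycomb protein cbx7a (-1.17, SE 0.22) and the neuronal pentraxin nptx2b (-1.14, SE 0.19).

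Matrix and muscle genes rose in smaller numbers at 10 dpf. Of 41 bone, tooth and fibroblast genes 8 rose, 15 when adjusted over the list alone, with the collagen genes col1a1a at 0.83 and col1a1b at 0.65 (camera adjusted p = 7.76e-08; adjusted p = 0.399 with an estimated correlation). Of 71 skeletal muscle genes 5 rose, among them the troponins tnni1a at 0.92 and tnnc2.2 at 0.84 (camera adjusted p = 4.96e-06; adjusted p = 0.434 with an estimated correlation). Of 50 photoreceptor genes 1 rose and 6 fell, the latter with pde6c at -0.70 and gucy2d at -0.84 (camera adjusted p = 0.0731). The visceral score was 5.16 ± 0.08 in knockdown and 5.07 ± 0.06 in controls.

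The count at 10 dpf was 515, of which 339 were higher and 176 lower, and it rested on single arrays. It was 105 without knockdown replicate 2, 122 without control replicate 2, 222 without knockdown replicate 1, 1060 without control replicate 1 and 1096 without knockdown replicate 3. With only the 6 arrays of this age in the fit, limma called 0 genes, with 1757 at an unadjusted p under 0.05. Median centring gave 292 higher and 292 lower genes. Over all genes, 14.3% had knockdown and control arrays that did not overlap, where chance gives 10%.

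At 15 dpf clock and p53 response genes and single pyruvate dehydrogenase kinase genes were higher in knockdown, and cholesterol synthesis and chaperone genes were lower. The pyruvate dehydrogenase kinases pdk2a, pdk2b and pdk4, which restrain glucose oxidation, rose by 1.77 (SE 0.20, adjusted p = 7.29e-06), 1.29 and 1.02. The collagen chaperone serpinh1b fell by 2.00 (SE 0.25, adjusted p = 2.51e-05) and manf, a secreted protein of the endoplasmic reticulum stress response, fell by 1.28 (SE 0.19). Of 22 cholesterol synthesis genes 10 fell, also 10 when adjusted over the list alone (median -0.31, camera adjusted p = 1.02e-08; adjusted p = 0.0972 with an estimated correlation). They include the early enzyme hmgcs1 at -0.82 and the squalene epoxidase sqlea at -0.92. Of 35 heat shock and unfolded protein response genes 13 fell and 2 rose, 15 and 2 alone (median -0.25, camera adjusted p = 1.21e-07; adjusted p = 0.392 with an estimated correlation), with hyou1 at -0.92 and hsp90aa1.2 at -0.87. Other large falls were in abcf2a (-1.42, SE 0.16), the co-chaperone dnajc21 (-1.37, SE 0.17) and the ammonium transporter rhcga (-1.21, SE 0.22). The cholesterol list mean in controls was 7.11 to 7.22 at 15 dpf, 6.49 to 6.59 at 10 dpf and 6.72 to 6.92 at 20 dpf. Knockdown at 15 dpf, at 6.71 to 6.97, overlapped the 20 dpf controls. For the chaperone list the control values were 8.41 to 8.57, 7.67 to 7.92 and 8.08 to 8.27, with 8.02 to 8.33 in knockdown at 15 dpf.

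Of 39 clock genes 17 rose at 15 dpf, 19 when adjusted over the list alone (median 0.39, camera adjusted p = 1.21e-06; adjusted p = 0.392 with an estimated correlation), with nfil3-2 at 1.17, rorcb at 1.07 and bmal1b at 0.84. Of 24 p53 response genes 9 rose and 1 fell (camera adjusted p = 0.0282; adjusted p = 0.491 with an estimated correlation), among them the autophagy regulator tp53inp1 at 0.94 and the cyclin ccng2 at 0.75. Of 24 genes of the mTORC1 pathway 5 rose and 1 fell, 9 and 1 alone (camera adjusted p = 0.0129; adjusted p = 0.392 with an estimated correlation). The risen genes include eif4ebp3l, a translation repressor, at 0.90 and the autophagy kinase ulk1b at 0.64, and the fallen gene is the S6 kinase rps6kb1b at -0.35. Of 39 insulin signalling genes 9 rose and 1 fell, 12 and 2 alone, with irs2a at 1.23, pdpk1a at 1.13 and the transcription factor foxo4 at 0.96 (camera adjusted p = 0.068). Of 22 inner ear genes 6 rose (camera adjusted p = 0.0371; adjusted p = 0.501 with an estimated correlation), with stm at 1.28 and s100t at 1.11.

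Single pancreatic and liver genes were higher at 15 dpf, while neither list passed its test. Of 31 exocrine pancreas genes 10 rose (median 0.47, camera adjusted p = 0.068), with cpb1 at 1.76 (SE 0.36) and ctrb.3 at 1.97 (SE 0.46), and of 45 liver genes 4 rose (median 0.21, camera adjusted p = 0.349). The visceral score, a mean that includes these genes, was 5.82 ± 0.27 in knockdown and 5.41 ± 0.22 in controls. In all 2316 genes differed, 1769 higher and 547 lower, and 1750 with the score as a covariate, chosen after seeing the data. Median centring gave 904 higher and 1080 lower genes and moved the median of all genes from 0.08 to -0.03. The count was 952 without knockdown replicate 1, 1222 without knockdown replicate 2, 1256 without control replicate 1, 1384 without control replicate 3 and 694 with only the 6 arrays of this age.

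At 20 dpf cholesterol synthesis and chaperone genes were higher in knockdown. The cholesterol pathway enzymes hmgcs1 and hmgcra, which catalyse its early steps, rose by 1.69 (SE 0.15) and 1.63 (SE 0.18), cyp51 by 1.47 (SE 0.15) and mvda by 1.36 (SE 0.14). Of the 22 genes of this list 18 rose, 20 when adjusted over the list alone (median 0.96, camera adjusted p = 4.24e-23), and it was the only list of the 14 called that held with an estimated correlation (adjusted p = 0.000676). Of 35 heat shock and unfolded protein response genes 22 rose, also 22 alone (median 0.59, camera adjusted p = 9.96e-16; adjusted p = 0.0628 with an estimated correlation), with manf at 1.91 (SE 0.19), hsp90aa1.1 at 1.68 and hyou1 at 1.29. The collagen chaperone serpinh1b rose by 1.91 (SE 0.25).

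Other rises at 20 dpf were in cell cycle and muscle genes and in single genes of other kinds. The nucleolar protein npm1a rose by 1.93 (SE 0.18, adjusted p = 8.17e-08), the coactivator pprc1 by 2.08 (SE 0.19, adjusted p = 7.88e-08) and abcf2a by 1.82 (SE 0.16). The secreted phosphoproteins of mineralised tissue scpp1 and scpp5 rose by 2.22 (SE 0.32) and 1.68, in a bone and tooth list of which 5 of 41 rose and 3 fell (median -0.05, mean 0.09, camera adjusted p = 0.97). Of 42 cell cycle genes 10 rose, 18 when adjusted over the list alone with 1 fallen, among them the replication genes mcm4 at 1.13, tyms at 1.18 and pcna at 1.07 (camera adjusted p = 2.3e-05; adjusted p = 0.518 with an estimated correlation). Of 71 skeletal muscle genes 16 rose, 21 alone, with myoz1b at 1.07 and the fast troponin tnni2b.2 at 0.92 (camera adjusted p = 2.47e-06; adjusted p = 0.439 with an estimated correlation). Of 65 oxidative phosphorylation genes 8 rose, with cycsb at 0.93 (camera adjusted p = 2.19e-05; adjusted p = 0.518 with an estimated correlation).

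Genes lower at 20 dpf included clock, insulin signalling and p53 response genes. The ubiquitin ligase adaptor klhl24b fell by 2.08 (SE 0.15, adjusted p = 1.38e-09), with falls also in the amino acid transporter slc43a2a (-1.82, SE 0.21), the cell death gene bbc3 (-1.45, SE 0.17) and the fatty acid synthesis gene acacb (-1.36, SE 0.14). Of 39 clock genes 12 fell and 1 rose, 17 and 2 alone, with the repressor nr1d1 at -1.37 (SE 0.26) and cipca at -0.83 (camera adjusted p = 3.15e-05; adjusted p = 0.402 with an estimated correlation). Of 39 insulin signalling genes 8 fell and 2 rose, 16 and 3 alone, with pdpk1a at -1.03, the receptor insrb at -0.59 and the phosphatase ptpn1 at 0.77 (camera adjusted p = 0.00591; adjusted p = 0.23 with an estimated correlation). Of 24 p53 response genes 4 fell, ccng2 at -0.92 and tp53inp1 at -0.87 among them (camera adjusted p = 0.0127; adjusted p = 0.402 with an estimated correlation). Of 24 mTORC1 pathway genes 7 fell, with sesn1 at -1.26 and eif4ebp3l at -1.10, and rps6kb1b rose by 0.66 (camera adjusted p = 0.0899).

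Of 45 liver genes 9 rose at 20 dpf (camera adjusted p = 0.0179; adjusted p = 0.836 with an estimated correlation), in arrays whose liver score was 5.54 ± 0.42 in knockdown and 5.08 ± 0.03 in controls. The largest, fetub at 4.02 (SD 2.74 in knockdown), no longer passed without knockdown replicate 1 (adjusted p = 0.0587) or knockdown replicate 2 (0.0597). The liver score too was 5.765 and 5.789 in knockdown replicates 1 and 2 but 5.053 in replicate 3, against 5.042 to 5.101 in controls. In all 2786 genes differed, 1956 higher and 830 lower, and 190 of the higher and 38 of the lower genes changed at least 2-fold. A second quantile normalization gave 1536 higher and 1384 lower genes, and median centring gave 1782 and 1371. Without control replicate 2 the count was 1742.

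**Figure D3:**
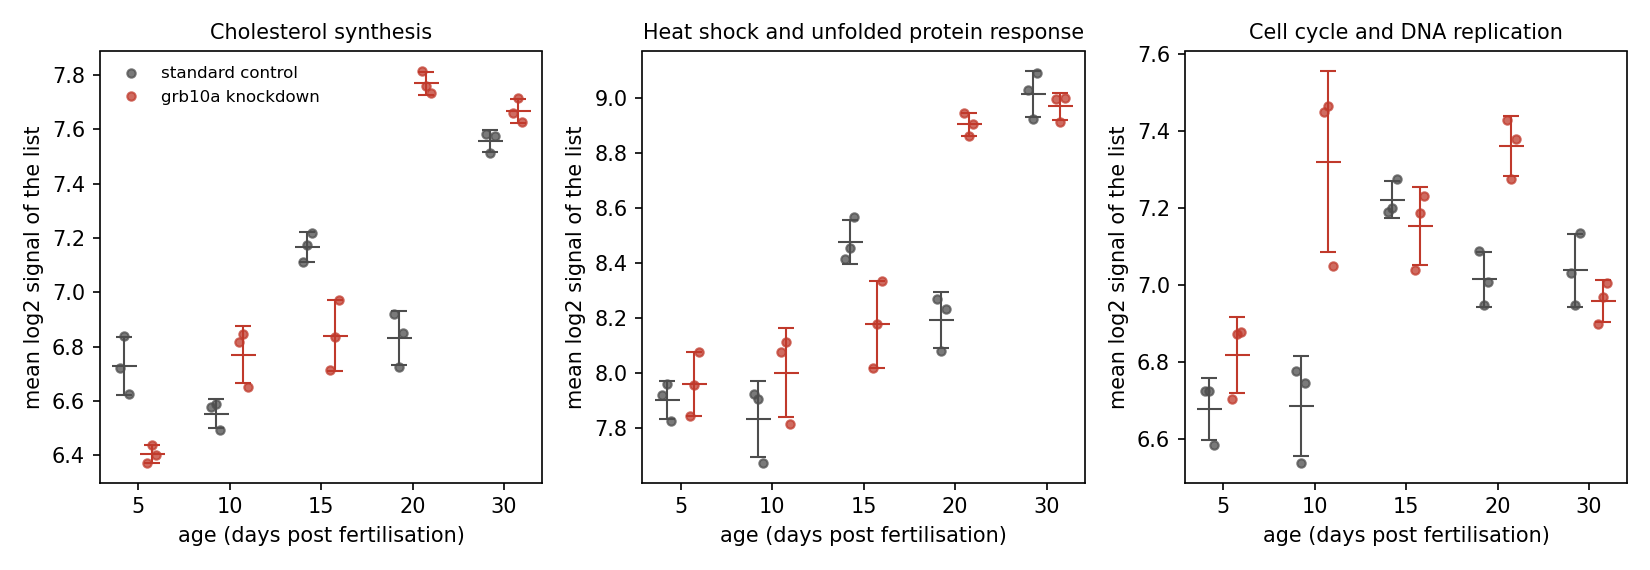
Mean log2 signal (vertical axes) of the cholesterol synthesis, heat shock and unfolded protein response, and cell cycle lists in each array by age in days post fertilisation (horizontal axes), with points for arrays and bars for the mean ± SD of 3 arrays in standard control (grey) and knockdown (red). Cholesterol list means at 20 dpf are 7.73 to 7.81 in knockdown and 6.72 to 6.92 in controls, while at 15 dpf they are 6.71 to 6.97 and 7.11 to 7.22.

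At 30 dpf 3 genes of the major histocompatibility complex (MHC), which present antigen, were lower in knockdown. The class I gene mhc1uba fell by 4.38 (SE 0.29, adjusted p = 3.63e-10), from 8.67 ± 0.37 to 4.29 ± 0.43, read as a lower limit because the knockdown level is under 6.06. The class I gene mhc1uka fell by 2.63 (SE 0.24, adjusted p = 1.55e-07) to 5.44. The class II gene mhc2daa fell by 2.53 (SE 0.46, adjusted p = 0.00277) to 4.67. Both are read as lower limits too. With only the arrays of this age in the fit mhc2daa no longer passed (limma, adjusted p = 0.105). Of 22 measured MHC class I and II genes these 3 fell and 2 rose, mhc1lfa by 1.28 (SE 0.21) and mhc2d8.35b2 by 1.07 (adjusted p = 0.0218), the latter chosen after its values were seen. The enamel matrix gene ambn fell by 2.04 (SE 0.17, adjusted p = 2.6e-08) and the insulin receptor substrate irs2a fell by 1.89 (SE 0.21, adjusted p = 4.9e-06). Other falls were in the astacin protease c6ast1 (-1.84, SE 0.20), the replication helicase gene mcm3 (-1.73, SE 0.29) and the matrix genes mfap4.12 (-2.01, SE 0.23) and paplnb (-1.63, SE 0.19). Of these mcm3 no longer passed with only the arrays of this age in the fit (limma, adjusted p = 0.0612). Rises were in the potassium channel kcnk5a (2.29, SE 0.18, adjusted p = 7.06e-09), ms4a17a.2 (2.04, SE 0.25) and the finTRIM gene ftr30 (1.27, SE 0.23). These 3 risen genes, mhc1lfa, mhc2d8.35b2 and the fallen genes mhc1uba, mhc2daa, ambn, c6ast1, mfap4.12 and paplnb have a mean signal over the 30 arrays in the lowest 33.3% of all genes. In controls at 30 dpf, however, these fallen genes lay above 6.06, at 8.67, 7.20, 8.16, 6.81, 8.11 and 6.49 in that order. The controls of kcnk5a, ms4a17a.2, ftr30 and mhc1lfa lay under it, at 5.93, 3.52, 5.23 and 3.32.

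Of 41 bone, tooth and fibroblast genes 4 fell at 30 dpf, 11 when adjusted over the list alone (median -0.20, camera adjusted p = 1.74e-06; adjusted p = 0.566 with an estimated correlation), with scpp7 at -1.11, loxl2b at -0.97 and col1a1b at -0.64 beside ambn. Of 39 insulin signalling genes 2 fell, irs2a and the catalytic subunit pik3ca at -0.72 (camera adjusted p = 0.0261; adjusted p = 0.566 with an estimated correlation). Of 22 cholesterol synthesis genes 1 rose, msmo1 at 0.54 (camera adjusted p = 0.00657; adjusted p = 0.584 with an estimated correlation). Of 31 exocrine pancreas genes only c6ast1 passed the test, and the median of the list was 0.50 (camera adjusted p = 7.23e-06; adjusted p = 0.566 with an estimated correlation). The liver and intestine lists had medians of 0.24 and 0.18 without any member past the gene test (camera adjusted p = 9.88e-05 and 0.00307; adjusted p = 0.706 and 0.566 with an estimated correlation). The visceral score was 5.56 ± 0.32 in knockdown and 5.29 ± 0.08 in controls. It was 5.926 in knockdown replicate 1 but 5.43 and 5.323 in replicates 2 and 3, against 5.235 to 5.382 in controls. The pancreas list mean was 6.259 in knockdown replicate 1. In replicates 2 and 3 it was 5.478 and 5.376, inside the control range of 5.132 to 5.486.

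In all 193 genes differed at 30 dpf, 70 higher and 123 lower. Of them 84 lie in the lowest 33.3% by mean signal over all 30 arrays, not by their signal at 30 dpf. Median centring gave 98 higher and 105 lower genes. The count was 103 without knockdown replicate 2, 117 without control replicate 1 and 117 without control replicate 3. In simulated data on these arrays the test recovered 49.6% of genes changed 1.5-fold, 89.3% changed 2-fold and 99.4% changed 4-fold. The simulated noise was independent between genes and each change was added in full whatever the signal. Recovery in the real arrays, above all of dim genes, may be lower.

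On average over the 5 ages, pancreas and liver genes were lower and cell cycle genes higher in knockdown. Of 31 exocrine pancreas genes 16 fell, 21 when adjusted over the list alone (median -0.52, adjusted p = 0.00249 with an estimated correlation), of 45 liver genes 23, 31 alone (median -0.45, adjusted p = 0.00539), and of 33 intestine genes 11, 14 alone with 1 risen (median -0.14, adjusted p = 0.00442). The visceral score behind these lists was 5.39 in knockdown and 8.09 in controls at 5 dpf, but its mean was higher in knockdown at each other age. It was 5.16 against 5.07 at 10 dpf, 5.82 against 5.41 at 15 dpf, 5.21 against 5.07 at 20 dpf and 5.56 against 5.29 at 30 dpf, so the average is set by 5 dpf. At 20 dpf only the liver mean was higher in knockdown (5.54 against 5.08). The pancreas (4.83 against 4.97) and intestine means (5.125 against 5.148) were lower. The score itself was not tested, and these later means lie under 6.06. Of 42 cell cycle genes 12 rose, 27 alone (median 0.20, camera adjusted p = 5.02e-15; adjusted p = 0.0823 with an estimated correlation). Their medians were 0.13, 0.68, -0.05, 0.29 and -0.03 at 5, 10, 15, 20 and 30 dpf (0.03 at 30 dpf with median centring), so the average is set mostly by 10 and 20 dpf. At 15 dpf 3 of them fell and none rose (camera adjusted p = 0.0213; adjusted p = 0.872 with an estimated correlation). The calcium-binding protein s100t rose by 0.61 (SE 0.08, adjusted p = 0.000178), the tight junction gene cldn1 by 0.48 (SE 0.10), the mitotic kinesin kif2c by 0.43 (SE 0.08) and the keratin krt1-19e by 0.41 (SE 0.06). The clock gene per3 fell by 0.55 (SE 0.08, adjusted p = 0.000337), and mfap4.12 fell by 0.63 (SE 0.10). The average of irs2a, chosen after its values were seen, fell by 0.62 (adjusted p = 0.000411) although it rose by 1.23 at 15 dpf. Of 39 clock genes 10 rose and 8 fell, with a median of 0.01 whose sign changed with the scaling of the arrays.

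The average contrast held 580 genes, 313 higher and 267 lower. A second quantile normalization gave 225 higher and 299 lower genes and median centring 261 and 360. Without 5 dpf 559 genes differed, 467 higher and 92 lower, 228 of them shared with the 580, and with the visceral score as a covariate 17 genes did; both alternatives were chosen after seeing the data. The score parts the treatments at 5 dpf and is built from the visceral genes, so the covariate lowers that count by construction. The count was 944 without control replicate 1 at 10 dpf.

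**Figure D4:**
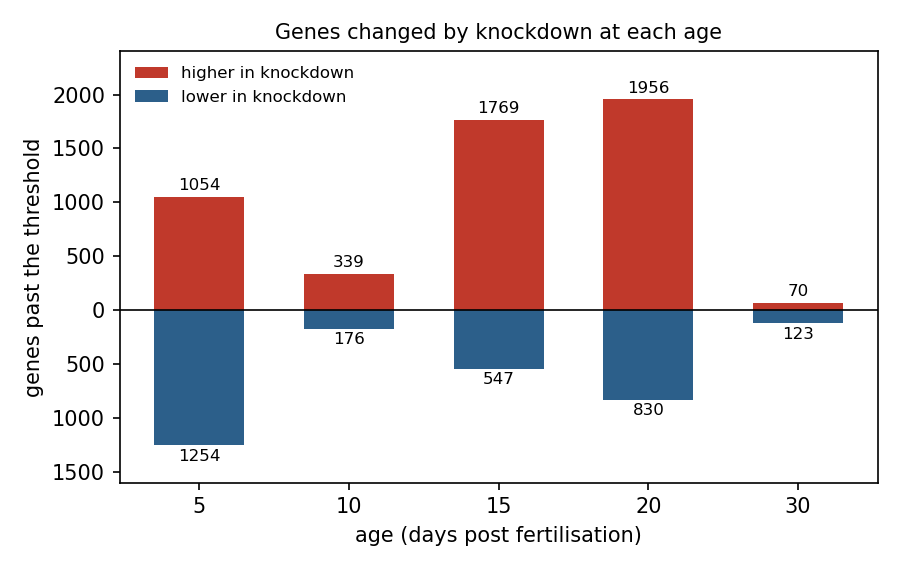
Number of genes that differed between knockdown and control (vertical axis), higher upward in red and lower downward in blue, at each age in days post fertilisation (horizontal axis), out of 19260 genes tested with 3 arrays per group. The counts are 1956 higher and 830 lower at 20 dpf and 70 and 123 at 30 dpf; which of 10 and 30 dpf has fewer changes with single arrays left out (105 to 1096 genes at 10 dpf), and the share of higher genes changes with the scaling of the arrays.

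The knockdown difference varied with age for 6105 of 19260 genes by the F test, 4078 without 5 dpf and 3578 with the visceral score as a covariate, both chosen after seeing the data. The named genes with the smallest p were the pancreatic gene sycn.2 (adjusted p = 6.16e-13), the inositol oxygenase miox (7.58e-13), and the carboxylesterase ces2b, the intestinal disaccharidase si and the amino acid transporter slc43a2b (each 6.53e-12). All 5 were lower at 5 dpf, where the visceral score was 5.39 in knockdown and 8.09 in controls.

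The 15 and 20 dpf differences ran opposite to each other across genes. Their correlation was -0.345, and 355 genes were higher at 15 and lower at 20 dpf where chance gives 76.2, while 344 were lower and then higher where chance gives 55.6. The cholesterol list differed between these ages by its own test (adjusted p = 6.64e-21; adjusted p = 0.00125 with an estimated correlation), and serpinh1b, manf, abcf2a, bbc3 and pdk2b are among the genes called in opposite directions. At 10 and 20 dpf the differences correlated at 0.286, with 119 genes higher at both (chance 34.4) and 34 lower at both (chance 7.6). At 10 and 15 dpf the correlation was -0.193 with a jackknife SE of 0.18, about as large as the value itself. It ranged from -0.257 without knockdown replicate 1 at 10 dpf to -0.067 without control replicate 1 at 10 dpf, so its sign is not established by this spread. Of genes called at both of these ages 51 were higher and then lower (chance 9.6) and 65 lower and then higher (chance 16.2). In a single direction 15 were higher at both (chance 31.1) and 1 lower at both (chance 5), but the calls at 10 dpf rested on single arrays. Genes are not independent replicates, so these values carry no p. No gene was called at all 5 ages, and 7 genes were called at 3 ages in a single direction. Of these the clock repressor nr1d2b was lower at 5, 10 and 20 dpf, by -0.49, -0.89 and -0.54, and crybg2 was higher at 5, 10 and 15 dpf, by 1.06, 0.99 and 0.64.

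In controls, genes of bone, muscle, lens and immune cells were higher at 30 than at 5 dpf, and genes of the viscera were lower. Knockdown differences were correlated across genes with control changes between other ages, which share no arrays with them. At 15 dpf the value was -0.185 (control change from 10 to 20 dpf) and at 20 dpf 0.225 (15 to 30 dpf). It was -0.239 at 5 dpf (10 to 30 dpf), 0.095 at 10 dpf (5 to 15 dpf) and -0.197 at 30 dpf (5 to 20 dpf). Whether the knockdown pools were ahead or behind in stage was not tested further. The tooth and bone gene scpp7 rose by 5.90 (SE 0.27), the class II chaperone cd74a by 5.73 (SE 0.25), the lens crystallin crygm2a by 5.19 (SE 0.20), the red cone opsin opn1lw1 by 4.77 (SE 0.25) and the troponin tnni2a.3 by 4.33 (SE 0.19). Of 41 bone, tooth and fibroblast genes 35 rose and 2 fell (median 1.77, camera adjusted p = 9.65e-16; adjusted p = 0.0538 with an estimated correlation), and of 71 skeletal muscle genes 57 rose and 4 fell (median 1.18, camera adjusted p = 1.12e-12; adjusted p = 0.0919 with an estimated correlation). Of 49 lens genes 26 rose and 5 fell (median 0.65, camera adjusted p = 0.00165; adjusted p = 0.44 with an estimated correlation), and 11 fell with median centring. Of 22 cholesterol synthesis genes 20 rose (camera adjusted p = 7.23e-06; adjusted p = 0.0919 with an estimated correlation), and of 35 heat shock and unfolded protein response genes 28 rose and 2 fell (camera adjusted p = 3.47e-08; adjusted p = 0.13 with an estimated correlation). Of 35 neutrophil and macrophage genes 22 rose and 1 fell (camera adjusted p = 0.00027; adjusted p = 0.118 with an estimated correlation), and of 29 lymphocyte genes 17 rose and 2 fell (camera adjusted p = 0.000854; adjusted p = 0.14 with an estimated correlation). Clock genes ran the other way, with 22 of 39 lower and 5 higher (camera adjusted p = 4.41e-06; adjusted p = 0.14 with an estimated correlation).

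Liver genes fell in 43 of 45 cases between 5 and 30 dpf (median -3.28, adjusted p = 0.00401 with an estimated correlation), exocrine pancreas genes in 27 of 31 (median -4.11, adjusted p = 0.00264) and intestine genes in 24 of 33 (median -1.65, adjusted p = 0.0014), with ctrb.3 at -6.43 and amy2a at -6.31. The visceral score of the controls was 8.09 at 5 dpf and 5.29 at 30 dpf. In all 9820 genes differed, 6576 higher and 3244 lower; median centring gave 4534 and 5357 and moved the median of all genes from 0.13 to -0.06. With 10 dpf as the start, chosen after seeing the data, none of the 10 genes with the largest falls was called lower. Of these prss59.1 rose by 2.05 (adjusted p = 0.00669) and apobb.1 by 1.54 (adjusted p = 0.0293), while ctrb.3 was at 0.55 (adjusted p = 0.326), and 9970 genes differed, 6829 of them shared.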

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

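The tests of delayed organ formation, of time of day and of exchanged labels were chosen after the results they concern had been seen, as were the division of Hox genes by group and the limit to 16 fasting-induced genes. The knockdown difference varied with age for 6105 genes and for grb10a (adjusted p = 2.53e-05). It also did for 85 of the 88 genes named at an age, but these were chosen for a large difference at 1 age, so that count is nearly fixed by the choice and supports nothing. In 100 regroupings within each age 1, the real one, gave as many genes varying with age (6105, highest other 2397). A share of 1 in 100 is under 0.05 and is the smallest that 100 regroupings can give. Regroupings that mix the treatments add any treatment difference to the spread within groups, which can lower their counts. Chance is thus not fully excluded for this count. For the average contrast 2 of the 100 gave as many genes (580, highest other 620). That share is under 0.05, but a regrouping other than the real one gave more genes. Chance is therefore not excluded for the average count either.

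Lists called in opposite directions at different ages were tested for the difference itself. They were picked by those calls, so the test with the preset correlation adds little to them. Given here are the 10 pairs of ages in which a list kept its difference with an estimated correlation. Other opposite pairs lost it, such as the clock list (adjusted p = 0.0616 with an estimated correlation) and the cell cycle list (0.0633) at 10 and 15 dpf. Skeletal muscle genes were lower at 5 dpf and higher at 10 dpf (adjusted p = 8.07e-21; 0.0266 with an estimated correlation) and at 20 dpf (2.8e-18; 0.0311). Cholesterol synthesis genes were lower at 5 dpf and higher at 20 dpf (1.32e-18; 0.00111), and lower at 15 dpf and higher at 20 dpf (6.64e-21; 0.00125) and 30 dpf (2.84e-10; 0.0496). Antioxidant genes were lower at 5 and higher at 20 dpf (1.34e-08; 0.0185). Liver genes were lower at 5 dpf and higher at 20 dpf (1.01e-47; 0.00111) and 30 dpf (1.21e-74; 7.2e-05), as were pancreas (1.12e-47; 4.76e-05) and intestine genes (3.43e-29; 2.31e-05) at 30 dpf; at 5 dpf the visceral score was 5.39 in knockdown and 8.09 in controls. These tests show that the ages differ, not that a list ran both ways. With an estimated correlation the rises opposite to 5 dpf were lost, for liver at 20 and 30 dpf (adjusted p = 0.836 and 0.706), pancreas and intestine at 30 dpf (0.566 each), muscle at 10 and 20 dpf (0.434 and 0.439) and antioxidant genes at 20 dpf (0.518), and no liver or intestine gene passed at 30 dpf. Cholesterol genes kept their call at 20 dpf (0.000676) and lost it at 5, 15 and 30 dpf (0.11, 0.0972 and 0.584).

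Named genes were also called in opposite directions at 2 ages, and since they were picked by those 2 calls a test of the difference adds no support. There were 12 such genes at 5 and 15 dpf, of which only 3 kept both calls without each array in turn (cpb1, ctrb.3 and inaa), and 4 did without knockdown replicate 3 at 15 dpf. The 9 that lost one were plac8.1, pdk2a, apoc2, prss59.1, apobb.1, cpa5, ela3l, ela2 and crygm2d17. None of the 3 at 5 and 20 dpf (apobb.1, fetub and hpda) passed at 20 dpf without knockdown replicate 1 (adjusted p = 0.133, 0.0587 and 0.0849) or 2 (0.163, 0.0597 and 0.0723). The 1 at 5 and 30 dpf, ms4a17a.2, did not pass at 5 dpf without control replicate 1 or 3 or knockdown replicate 3 (0.0947, 0.132 and 0.114). Of 7 at 10 and 15 dpf 4 kept both calls, irs2a among them, while bhlhe40, pdk2a and cbx7a did not. Of 17 at 15 and 20 dpf 14 did, serpinh1b and bbc3 among them, and npm1a, ca15c and nudc did not. Of 2 at 15 and 30 dpf irs2a did and paplnb did not, and the 1 at 20 and 30 dpf (mcm3) did.

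The first pattern is the fall of visceral genes at 5 dpf, where the control pools, and not the knockdown pools, stand apart from all later ages. Delayed organ formation in the knockdown was taken to predict that controls keep these transcripts at 10 dpf. The controls' own change from 5 to 10 dpf covered 111% of the 5 dpf difference. That loss in controls was known when the test was chosen, and its cause was not tested. It shows that controls need not keep these transcripts, so the test cannot decide on a delay at 5 dpf. Trunk tissue carried into the control pools at dissection predicts lower Hox genes of the body axis in knockdown, and the median of 32 such genes was -0.258, under the 5th percentile of matched random lists (-0.18), though only 7 lay above the dim limit of 6.06 in controls at 5 dpf (median -1.08), and the 5 called lower belong to groups 5, 6 and 8 while group 13 had a median of 0.21. That is in line with more tissue from just behind the head in the control pools at 5 dpf, which may also bear on the muscle and kidney genes and, by thinning out head tissue in controls, on the higher photoreceptor, neuron and lens genes (medians 0.45, 0.20 and 0.21), though other lists of the head did not rise with them (glia and inner ear both at -0.09). A knockdown effect on liver and pancreas themselves stays open, untested.

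The second pattern is the opposite change of cholesterol genes and, with the preset correlation only, of chaperone genes at 15 and 20 dpf (adjusted p of the chaperone difference 1.32e-14; 0.0832 with an estimated correlation). At 15 dpf the control pools lay above the controls of 10 and 20 dpf in both list means, while the knockdown pools overlapped the 20 dpf controls. Feeding state at collection predicts that fasting-induced genes are higher at 15 and lower at 20 dpf, and 16 such genes outside the fixed lists and the named genes had a median of 0.308 at 15 dpf (7 rose, upper limit of matched random lists 0.273) and -0.253 at 20 dpf (7 fell, lower limit -0.14); all 41, in part already reported, had 0.444 and -0.281. The 16 genes also lay under the lower limit at 5 dpf (-0.102, limit -0.093) and 10 dpf (-0.134, limit -0.082), but not at 30 dpf (-0.126, limit -0.148). The random lists were matched on mean signal and not on how far genes move together, so these limits may be too narrow. A difference in feeding between the pools is a candidate explanation, though a change of insulin signalling by the knockdown could move the same genes. Time of day cannot be told apart, because the difference of the 2 clock arms was -0.30 at 15 dpf and -0.45 at 20 dpf, large at both ages, as at 5 dpf (-0.915), but without the opposite sign predicted, and unequal shifts in time could give either sign. Both arm medians were above 0 at 15 dpf (day 0.24, night 0.54) and below 0 at 20 dpf (day -0.59, night -0.14). Only at 5 dpf did the arms lie clearly on opposite sides of 0 (day -0.34, night 0.58). An exchange of knockdown and control labels at 15 dpf cannot be told apart from a true turn, since both predict the -0.345 with 20 dpf (SE 0.115) and the 0.286 between 10 and 20 dpf (SE 0.056), while the sign of the -0.193 with 10 dpf is not established by its spread (SE 0.18, -0.067 without control replicate 1 at 10 dpf). Calls at 10 and 15 dpf were opposite more often than by chance (51 against 9.6 and 65 against 16.2) and alike less often (15 against 31.1 and 1 against 5). An exchange and a true turn both predict that too.

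The third pattern is the fall of 3 of 22 MHC genes at 30 dpf, where 2 others rose. Lower antigen presentation as a programme predicts lower partner genes, whose median over 10 genes was -0.014, with 0 of them past the test. As a set the partners were thus not lower. The mean signals of psmb8a, tapbp.1, ciita, psmb9a and cd74b over all 30 arrays lie under the dim limit of 6.06. Their levels at 30 dpf may differ from these means. Of the brighter partners b2m was at -0.53 and tap1 at 0.27. The test therefore does not exclude this explanation. Different MHC haplotypes among the pooled fish were taken to predict large differences at other ages too, and 0 of the 4 other ages showed them. The limit set was wrong. In controls at 5, 10, 15 and 20 dpf only 4, 3, 5 and 5 of the 22 genes lay above 6.06, the dim limit. Of those genes 0 were called at these ages. The pools of each age also hold other fish, so haplotypes that differ at 30 dpf need not differ at other ages. This explanation therefore cannot be told apart. Of the fallen genes, mhc1uka differed by 0.05 and 0.04 at 15 and 20 dpf at control levels of 6.37 and 6.42. The gene mhc1uba differed by 0.18 at 20 dpf at a control level of 6.13. Both lay only a little above the dim limit, and for the same reasons these values do not decide. A knockdown effect on single MHC genes stays open too, untested.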

How the results depend on the processing

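The visceral score as a covariate, the removal of genes that follow it, leaving out 5 dpf and 10 dpf as the start were chosen after seeing the data. A count held when within 1.5 times its main value, a correlation when within its jackknife SE, and a tested value when it kept its sign and side of the threshold. Of the values of comparisons under all alternatives 364 held, 4 newly passed and 41 moved; of those of named genes 2313 held, 213 no longer passed and 8 reversed; of those of gene lists 132 held and 132 no longer passed; where not said otherwise the cause was not tested. All 8 reversals came with 10 dpf as the start of the age comparison in controls, by which time the visceral genes had already fallen: ctrb.3 0.55, prss59.2 1.36, amy2a 0.043, prss59.1 2.05, cpa5 0.81, apobb.1 1.54, prss1 0.81 and ela2 0.55, of which prss59.1 and apobb.1 passed (adjusted p = 0.00669 and 0.0293). The 15 dpf difference of grb10a, 0.33, passed with an intensity trend (adjusted p = 0.0471), without dim genes (0.0394) and with a replicate block within each age (0.0486), and over left-out arrays it ranged from 0.30 to 0.39. By the limit set the numbers do not pair the samples, since 4 of 15 pairs correlated above 0.1. As a hint from the data the other way, 19 of 30 arrays correlated best with their own number where chance gives 10, with all 6 at 20 dpf and all 6 at 30 dpf. With the replicate block the counts were 2244, 483, 2428, 2843 and 212 at 5, 10, 15, 20 and 30 dpf.

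With single arrays left out, counts ranged from 1538 to 2043 at 5 dpf, 105 to 1096 at 10 dpf, 952 to 2715 at 15 dpf, 1742 to 2256 at 20 dpf, 103 to 175 at 30 dpf and 420 to 944 on average, the correlation of 10 and 20 dpf from 0.23 to 0.288 and that of 10 and 15 dpf from -0.257 to -0.067. With only the compared arrays limma called 1442, 0, 694 and 119 genes at 5, 10, 15 and 30 dpf (1757 at 10 dpf at an unadjusted p under 0.05), but more at 20 dpf (3167) and with age (10382). Array weights gave 4787 at 20 dpf, 493 at 30 dpf and 1100 on average. All probe sets one by one, more tests by construction, gave 722 at 30 dpf and 24659 with age; without dim genes 30 dpf had 124. With the visceral score as a covariate 17 genes differed on average and 3578 varied with age. An estimated correlation left 7, 1, 0, 1, 0 and 3 lists at 5, 10, 15, 20, 30 dpf and on average, against 23, 13, 9, 14, 11 and 18 by the preset; fry called 5 at 10 dpf, 11 at 15 dpf, 1 at 30 dpf and 8 on average, and 4 and 2 lists had an unadjusted p under 0.05 by an estimated correlation at 15 and 30 dpf. Correlations without dim genes were -0.214 for 5 and 20, 0.368 for 10 and 20 and -0.469 for 15 and 20 dpf, and Spearman gave -0.012 for 5 and 15 dpf. Grb10a has 1 probe set, so no alternative probe set could be tried. Dim signals may limit the 30 dpf count. Of its 193 genes 84 are dim by the mean over all 30 arrays, which need not hold at 30 dpf. One of them, mhc1uba, was at 8.67 in controls of that age.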

Other observations

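At 30 dpf single pigment epithelium, lens and ionocyte genes were lower in knockdown, and none of the 3 lists passed with an estimated correlation. Of 17 genes of the retinal pigment epithelium and pigment cells 3 fell, the visual cycle genes rpe65a at -1.21 and rlbp1b at -0.85 and the retinol transporter stra6 at -0.52 (camera adjusted p = 0.0208; adjusted p = 0.706 with an estimated correlation). Of 49 lens genes 2 fell, the crystallin genes crybb3 and cryba1a, the latter at -1.48 (camera adjusted p = 0.332), while the crystallin genes crygm2d17 and crygm2e were at 1.22 and 0.64 without passing the test. Of 22 ionocyte genes 4 fell, with the sodium chloride cotransporter slc12a10.2 at -0.94 and the chloride channel clcn2c at -0.85 (camera adjusted p = 0.344). The inner ear gene s100t rose by 1.25 and the endoplasmic reticulum co-chaperone dnajb11 by 0.94.

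Single globin, mucosa and complement genes also differed. At 10 dpf the globin genes hbae1.1 and hbae3 rose by 1.06 and 0.84, and at 20 dpf hbae3 rose by 1.42. The goblet cell genes agr2 and muc5.2 rose by 1.55 and 1.26 at 20 dpf, where 10 of 46 epidermis and mucosa genes rose (camera adjusted p = 0.0786). At 5 dpf the complement genes c3a.1 and c9 were at -3.98 and -3.44 and the glycolysis gene gapdh fell by 2.21, beside the visceral score of 5.39 in knockdown and 8.09 in controls. At 15 dpf the interferon signalling gene stat2 rose by 1.22 and the lens chaperone cryaa by 1.42.

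For each contrast of 3 against 3 arrays there are 10 splits, too few for a share under 0.05. Only 1 split, the real one, gave as many genes at 5 dpf (2308, highest other 0), 15 dpf (2316, highest other 0), 20 dpf (2786, highest other 0), 30 dpf (193, highest other 5) and with age in controls (9820, highest other 0). At 10 dpf 2 splits did: the split of control replicate 1 with knockdown replicates 1 and 2 against the other arrays gave 1530 genes, against 515 for the real one, which points to a structure of these 6 arrays other than treatment.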
